A study of Tetranychus urticae with 8 samples.

How the data were processed

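Gene expression was measured by RNA sequencing in whole bodies of adult two-spotted spider mites (Tetranychus urticae, strain London), a plant-feeding mite, kept on leaves of common bean. Per the labels' protocols, total RNA was taken with a column kit from about 800 males or about 200 females per library, the males being collected at an age of 1 to 2 days and the females at 3 days. Libraries were strand-specific and selected for poly(A) RNA with oligo dT, per the same protocols. Age and number of pooled animals therefore differed between the sexes in every library and cannot be told apart from sex in any comparison.

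The deposited values are whole-number counts of reads per gene ID, 1 column for each of the 8 libraries, with no normalization, per the file headers and the values themselves. The submitters' processing notes name STAR version 2.4.1d and HTSeq version 0.6.1 without saying how they were set. The genome build, the annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. Depending on those settings, genes that share sequence with a near copy or overlap another gene can lose reads or receive those of the other. The table held 17654 gene IDs, 0 rows that named no gene, and 0 columns left unused. Of these IDs, 1513 had no read in any library.

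Each column was assigned to a sample by its name, which is written in that sample's description, and each sample to a sex by its title. The labels describe the 4 libraries of each sex as biological replicates but do not say whether they came from separate cultures, so p-values measure the spread between these pools. The sum of reads over genes ranged from 12082575 to 21414612 per library. This puts the level of 3 reads between 0.142 and 0.248 in counts-per-million units (CPM), scaled like the CPM values of the tested genes. Such limits cover counting error only.

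The files do not pair the IDs with gene names. Of the 17654 IDs, 0 occurred in the gene table of the species used here, so no gene is described by function and no coordinates are given. The 36 gene lists that had been fixed before the data were examined, as search patterns for gene names and descriptions, could not be filled, and no gene list was tested. Under the rule fixed for this case, 2 IDs per direction are named: those with the highest and the lowest fitted log2 fold changes among genes past both thresholds, at 10 CPM or more on average in the higher sex and with no overlap between female and male libraries. A pair of IDs named outside this rule was chosen after its values were seen, as is said where it is described.

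Females were compared with males by the quasi-likelihood F test of edgeR version 4.0.16 in R version 4.3.3, with sex as the only term, scaling by the trimmed mean of M values (TMM) and low-count genes removed by filterByExpr. This left 12885 genes for testing, which held at least 99.9% of the reads of every library. The p-values were adjusted by the Benjamini-Hochberg method, and a gene was called higher in a sex at an adjusted p below 0.05 and a fitted fold of at least 2. Fold changes are log2 values of female minus male, and CPM values are scaled by the same factors. Fitted fold changes of genes with no read in one sex depend on the prior count of the fit, so such genes were also set at the fold against 3 reads over the 4 libraries of that sex. Standard errors of log2 fold changes are the fold change divided by the square root of F. Genes were described as sex-limited, without a test, when every library of one sex had at least 10 reads and the 4 libraries of the other had at most 3 in total. Values per library were compared by exact two-sided permutation tests over the 70 assignments of the libraries, whose smallest possible p is 0.0286.

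The alternatives fixed before the data were examined were 4 other scalings (DESeq2's size factors, upper quartile, total counts, and 500 genes of low spread), no filter and a filter at 5 CPM in 4 libraries, DESeq2 version 1.42.0, limma-voom with limma version 3.58.1, edgeR's glmTreat against a fold of 1.5, the replicate number as a block, and leaving out each library in turn. Libraries thinned to 12082575 reads each, counts of sex-limited genes without one run of IDs, and the difference in detected IDs with each library left out, were added after the data were seen, as were the classes of fold and abundance, their counts under other scalings and the bounds for genes with no read in one sex. The edgeR step was tested on simulated counts drawn from the real means, library sizes and dispersions, with 200 changed genes among 12718 fitted. At an adjusted p below 0.05 it recovered 42 of 50 genes changed by 1.5-fold, 44 of 50 changed by 2-fold, 50 of 50 changed by 4-fold and 50 of 50 changed by 8-fold in the right direction, with 9 false calls among 195. The 2-fold minimum was not applied there. In the real data 11580 of the 12885 tested genes differed. The simulation therefore did not test the scaling or the false calls where most genes differ. Orders of IDs were tested by 100000 random shuffles.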

Results

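The transcriptomes of adult females and adult males of the two-spotted spider mite were compared to find the genes that differ in expression between the sexes. Spider mites are haplodiploid, so that males develop from unfertilized eggs and females from fertilized eggs. There were 4 libraries of pooled females and 4 of pooled males. The female libraries held 12912850 to 17443223 reads on genes and the male libraries 12082575 to 21414612, and the difference in mean depth was smaller than the spread between libraries (exact permutation p = 0.629). Females and males also differed in age and in the number of pooled animals, so every difference given here is between these groups as collected. The levels are those of whole bodies and are not resolved by tissue or cell type.

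Most of the transcriptome differed between the sexes. At least 2-fold differences at an adjusted p below 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg) were found for 3467 genes that were higher in females (26.9% of the 12885 tested) and 3935 that were higher in males (30.5%). A further 4178 genes differed by less than 2-fold, so that 11580 genes (89.9%) differed at some size and 1305 did not pass the test. Over all tested genes, called or not, the 4 female and 4 male libraries did not overlap in 11107 (86.2%), against 2.86% of genes by chance. The median log2 fold change of all tested genes was -0.05. Upper quartile scaling moved that median to -0.27 and the counts to 3011 higher in females and 4456 higher in males, so fold changes are given relative to TMM scaling.

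**Figure D1:**
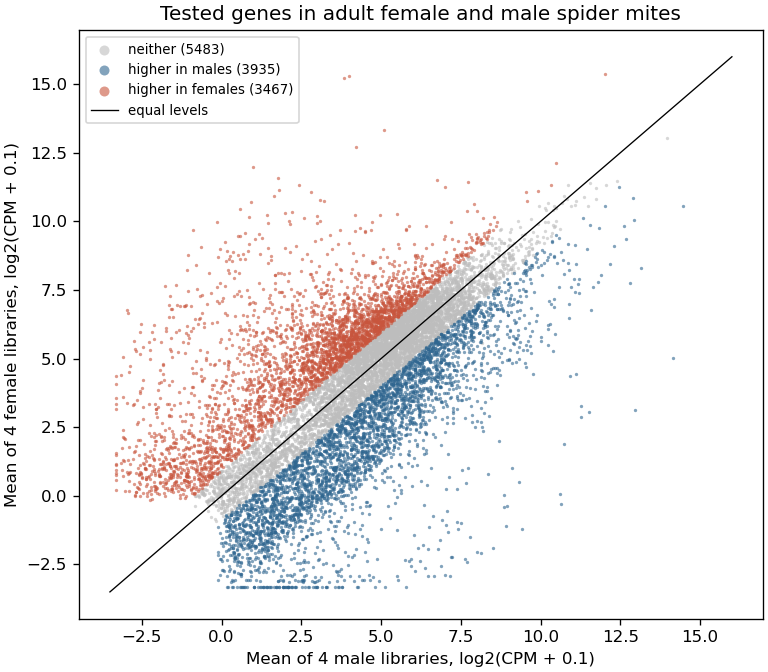
Mean expression of each of the 12885 tested genes in the 4 male libraries (x axis) and the 4 female libraries (y axis), both as log2(CPM + 0.1), coloured by whether the gene was higher in females (3467), higher in males (3935) or neither. The line marks equal levels, and points at the left and lower edges are genes with almost no reads in one sex.

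The highest fitted log2 fold changes among genes at 10 CPM or more belonged to tetur14g01460 and tetur43g00010, both higher in females. The gene tetur14g01460 had 1402 to 1805 reads in each female library and 2 reads in the 4 male libraries together, a ratio of 3406 after scaling (95% exact counting interval 943 to 28132; adjusted p = 4.15e-17 by edgeR). The gene tetur43g00010 was the third most abundant transcript of females, with 38219 ± 5034 CPM (SD, n = 4) or 3.82% of the reads, against 14.3 ± 4.2 CPM in males. Its log2 fold change was 11.39 ± 0.21 (SE; adjusted p = 4.96e-16 by edgeR).

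The lowest fitted log2 fold changes belonged to tetur07g08035 and tetur01g06790, both detected in males alone. Fitted values of genes with no read in one sex depend on the prior count of the fit, so these genes are not ranked against others by their bounds. The gene tetur07g08035 had 609 to 1209 reads in each male library, or 54.6 ± 4.1 CPM (SD, n = 4), and 0 reads in the 4 female libraries. Taking 3 reads over the 4 female libraries as the limit that a count of 0 allows, it was at least 1051-fold higher in males (adjusted p = 1.09e-13 by edgeR). The gene tetur01g06790 had 405 to 705 reads in each male library, or 34.4 ± 1.3 CPM, and 0 reads in females, so that it was at least 662-fold higher in males (adjusted p = 2.05e-13 by edgeR).

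Expression close to restricted to one sex was seen for 165 genes in males and 54 in females. The male-limited genes had at least 10 reads in each male library and at most 3 in the 57493789 reads of the female libraries together, a limit of 0.0520 CPM. Their median level in males was 4.02 CPM, and 35 of them exceeded 10 CPM. The female-limited genes had a median of 2.41 CPM in females, 16 of them exceeded 10 CPM, and the corresponding limit in the 62804066 male reads was 0.0480 CPM. With 0 reads required in the other sex, 75 male-limited and 14 female-limited genes were counted, and with at least 20 reads per library 35 female-limited genes. Both counts rose when a library of the other sex was left out, which makes the limit of 3 reads easier to meet. The female-limited count was 84, 95, 71 and 85 without male replicates 1, 2, 3 and 4. The male-limited count was 201, 192, 196 and 188 without female replicates 1, 2, 3 and 4. The gene tetur43g00010, with 159 to 280 reads in each male library, is not among the female-limited genes. No gene at 1000 CPM or more in one sex met the limit of 3 reads. The lowest mean of such genes in the other sex was 0.810 CPM in males and 0.707 CPM in females. The counts therefore hold only genes of up to 143 CPM in males and 110 CPM in females. The source of the few reads that abundant genes had in the other sex was not examined.

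Of the 165 male-limited genes, 51 had IDs that stood within a single stretch of 58 consecutive tested IDs, the last of the 552 tested IDs that begin with tetur09. In that stretch 56 of the 58 genes were higher in males. The summed level of all 58 was 377 ± 16 CPM in males and 18.2 ± 0.7 CPM in females (SD, n = 4 each). Of the 56, 51 had at most 3 reads in the 4 female libraries together, and the median of the 56 there was 0 reads. The female sum therefore came mostly from the other genes of the stretch. The stretch was singled out after its values were seen. Outside the stretch there were 114 male-limited genes. Reads shared between similar copies could not be examined for it.

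**Figure D2:**
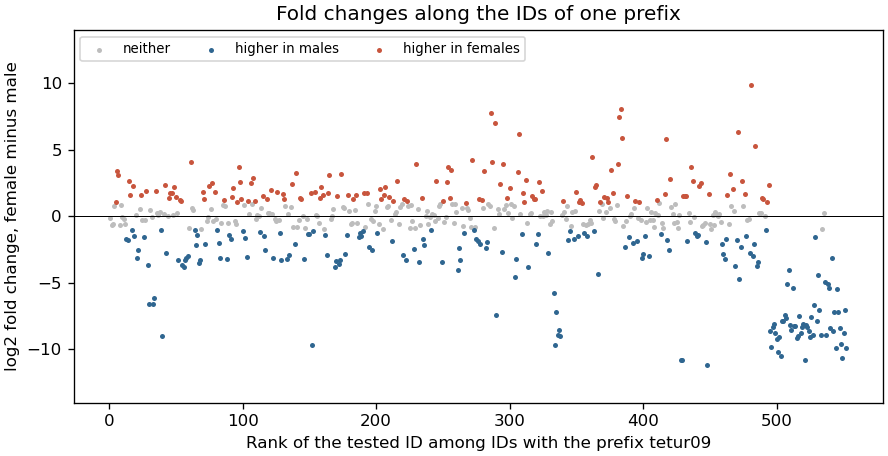
Log2 fold change, female minus male (y axis), of the 552 tested genes whose IDs begin with tetur09, in the order of their IDs (x axis), coloured by call. The last 58 points hold 56 genes that were higher in males, 51 of them male-limited.

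The most abundant transcript of females stood at 42757 ± 676 CPM and was also present in males, at 4199 ± 190 CPM (SD, n = 4 each). The second most abundant, by contrast, had 39809 ± 1503 CPM in females and 15.9 ± 5.0 in males. The most abundant transcript of males had 22528 ± 1674 CPM in males and 1510 ± 103 in females, and the second had 18241 ± 1432 CPM in males and 32.4 ± 1.6 in females. A single gene was among the 5 most abundant of both sexes, with 15821 ± 637 CPM in males and 8407 ± 269 in females. Its log2 fold change was -0.91 ± 0.05 (SE; adjusted p = 2.91e-10 by edgeR), which is below the 2-fold minimum.

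The few most abundant transcripts took a larger share of the reads in females than in males. The 10 most abundant genes of each library held 16.2% ± 0.5 of the reads in females and 10.9% ± 0.4 in males (SD, n = 4 each; exact permutation p = 0.0286). The most abundant gene of each library, which was not the same gene in all female libraries, held 4.30% ± 0.04 in females and 2.24% ± 0.18 in males. The shares of the 50 most abundant genes were closer, at 23.9% ± 0.4 in females and 22.8% ± 0.2 in males, a difference of 1.14 percentage points (exact permutation p = 0.0286). The order reversed for the 200 most abundant genes, which held 35.6% ± 0.4 in females and 37.9% ± 0.2 in males (exact permutation p = 0.0286). Of the 50 genes with the highest mean in each sex, 16 were on both lists. Of the 50 of females, 24 were higher in females and 4 in males. Of the 50 of males, 38 were higher in males and 1 in females.

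The genes that differed carried much of the RNA of each sex. Genes higher in females took 49.0% ± 0.3 of the reads in female libraries and 7.86% ± 0.05 in male libraries (SD, n = 4 each). Genes higher in males took 48.5% ± 0.2 of the reads in male libraries and 9.25% ± 0.30 in female libraries. Both differences were the largest the exact permutation test can register (p = 0.0286), and the genes were chosen on these same libraries, so the shares describe the calls and are not independent evidence of them.

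The genes higher in males and those higher in females were spread differently over sizes of difference and levels of expression. Among genes higher in females, 1730 differed by 2- to 4-fold, 1183 by 4- to 16-fold, 456 by 16- to 256-fold and 98 by 256-fold or more. Among genes higher in males the corresponding counts were 1632, 1812, 366 and 125, with 46.0% of them in the 4- to 16-fold class against 34.1% of the genes higher in females. The order in the highest class depends on genes with no read in the other sex. There were 74 of these among the genes higher in males and 14 among those higher in females. With these set at the fold against 3 reads, the class held 74 genes higher in males and 92 higher in females, the opposite order. The median size of the log2 fold change was 2.00 for genes higher in females (quartiles 1.42 and 3.15). It was 2.30 for genes higher in males (quartiles 1.52 and 3.24). The bounds could not change these medians, since 554 genes higher in females and 491 higher in males were at 16-fold or more with and without them. Genes higher in females had a median of 43.5 CPM in female libraries, and genes higher in males a median of 19.3 CPM in male libraries.

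**Figure D3:**
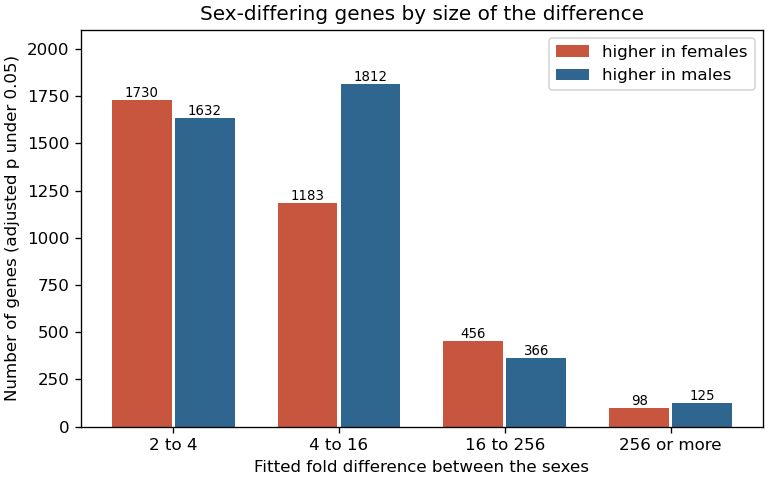
Number of genes past the threshold (y axis) in 4 classes of fitted fold difference between the sexes (x axis), for genes higher in females and genes higher in males. The 4- to 16-fold class held 1183 genes higher in females and 1812 higher in males, and the order in the class of 256-fold or more depends on how genes with no read in one sex are treated.

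The direction of the difference varied with abundance. The tested genes were divided by average abundance into 5 classes of 2577 genes. In the lowest class (0.573 to 3.87 CPM), 1116 genes were higher in males and 659 in females, and in the next (3.87 to 15.4 CPM) the counts were 1051 and 623. More genes were higher in males than in females in both of these classes under each of the 4 other scalings. In the middle class 643 genes were higher in males and 815 in females, but 733 and 705 with upper quartile scaling. In the class from 37.5 to 83.3 CPM the counts were 526 higher in males and 749 in females, and 620 and 638 with upper quartile scaling. In the most abundant class they were 599 and 621, an order that turned to 729 and 513 with upper quartile scaling and to 612 and 602 with scaling on 500 genes of low spread.

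**Figure D4:**
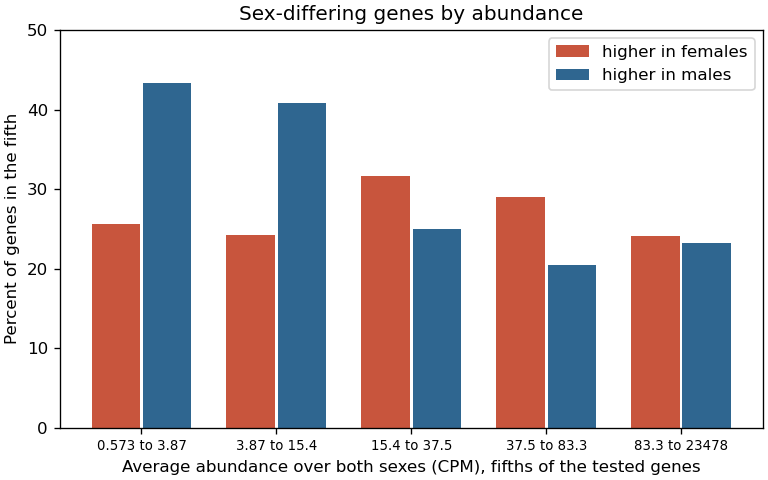
Percent of the genes in each of 5 classes of average abundance (x axis, CPM over both sexes, 2577 genes per class) that were higher in females or higher in males (y axis), under TMM scaling. In the lowest class 43.3% of genes were higher in males and 25.6% in females; in the class from 37.5 to 83.3 CPM the values were 20.4% and 29.1%, and the order in the middle and the most abundant class turned with upper quartile scaling.

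More gene IDs were detected in males than in females. At least 1 read was found for 14888 ± 189 IDs in male libraries and 14441 ± 113 in female libraries (SD, n = 4 each; exact permutation p = 0.0286). With every library thinned to 12082575 reads the numbers were 14728 ± 62 and 14326 ± 46 (exact permutation p = 0.0286).

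Libraries of the same sex were close to one another and far from those of the other sex. The correlation of log2 CPM across the 12885 tested genes was 0.989 to 0.993 between male libraries and 0.992 to 0.994 between female libraries, but 0.648 to 0.665 between a female and a male library (genes are not independent replicates). The first principal component held 96.7% of the variance and the second 0.710%. The biological coefficient of variation estimated by edgeR within a sex was 0.0868 in males and 0.0649 in females. No pair of libraries of a sex agreed within sampling noise: the chi-square statistic per degree of freedom ranged from 3.37 to 20.2 over the pairs, against an expectation of 1 for repeated reads of a single library.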

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

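The counts of genes higher in females and higher in males stayed within 1.5 times their reported values in all 18 alternatives to the main test, as did the count differing at any size in all of them but glmTreat, which gives no such count. They ranged from 2716 to 4226 higher in females and from 2966 to 4620 higher in males, with 0 genes called in opposite directions, and at least 75.1% of the reported calls were shared in each; the lowest counts came with the filter at 5 CPM, which tests 10235 genes. Males made up 51.8% to 59.7% of the calls, the highest with upper quartile scaling. The replicate numbers did not pair the samples: deviations of same-numbered females and males correlated at -0.09, 0.0017, 0.019 and 0.035, 1 of the 8 samples correlated best with its own number, and with the replicate block 3472 genes were higher in females and 3932 in males. The 4 named genes kept their direction and an adjusted p below 0.05 in each of these 18. DESeq2 gave no adjusted p for 5 genes. The male-limited count fell from 165 to 75 with 0 reads allowed in females. The female-limited count fell from 54 to 35 with at least 20 reads per library and to 14 with 0 reads allowed in males, and ranged from 55 to 95 as single libraries were left out; fewer libraries make the limit of 3 reads easier to meet. The share of reads in the most abundant genes was 1.14 points higher in females for 50 genes and reversed to -2.22 for 200. Leaving out a library gave 0.999 to 1.28 points for 50 genes, and -509 to -376 for the difference in IDs with a read (female minus male); with 3 against 4 libraries the exact test cannot go below p = 0.0571, so these do not pass by construction. The tests of gene lists planned before the data were examined were not run, since no ID could be given a name, and 500 genes of low spread took the place of ribosomal protein genes in the scaling. Depth limits what near absence in one sex can mean, since 3 reads are 0.142 to 0.248 CPM in a single library.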

Other observations

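The patterns in this part were found in these data. The tests on other splits of the libraries, on shuffled orders of IDs, on the spread of the run's total, on the pair of IDs and on female material in male pools were specified after their results had been seen; those on the low-abundance genes, on thinning of the run and on adjacent IDs without the run were specified before, although the total counts of calls under each scaling were already known. Of the 35 splits of the 8 libraries into 4 and 4, only the split by sex gave as many genes higher in females (3467, highest other 0), higher in males (3935, highest other 0) or differing at any size (11580, highest other 0). For each count this is 1 of 35, the smallest share these splits can give. Every other split mixes the sexes within its groups, so the counts of 0 do not measure how many calls arise by chance among libraries of like kind.

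For genes with at least 1000 CPM in one sex, the largest fold differences were of like size in both directions. The largest ratio of means was 2678 among the 77 such genes of females and 2265 among the 111 of males. The lowest mean of any of these genes in the other sex was 0.810 CPM in males and 0.707 CPM in females.

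Among male libraries a small set of genes rose and fell together. At over 5 CPM on average, 45 genes differed by at least 3-fold between the highest and lowest male library, against 9 genes between female libraries. Of the 45, 22 were highest in male replicate 3 and lowest in male replicate 4, the most frequent of the 12 possible combinations, followed by one with 8 genes. All 22 had higher means in males than in females, and 21 were called higher in males. Their median level relative to the male mean was 1.31, 0.732, 1.61 and 0.327 in male replicates 1 to 4. Dilution by female material in the male pools is argued against. Taken against the mean of the male libraries, dilution would need a share of at least 67.3% in male replicate 4. There the 10 most limiting of the 43 female-higher genes at 1000 CPM or more in females each allow at most 0.1954%.

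Genes whose IDs do not end in 0 were higher in males more often than the rest. Of the 727 such IDs, 292 were tested, and 139 of these (47.6%) were higher in males and 63 (21.6%) in females. Among the 12593 tested IDs that end in 0, 30.1% were higher in males and 27.0% in females (odds ratio for higher in males 2.11, 95% interval 1.66 to 2.68; Fisher's exact p = 6.79e-10, with genes as the units). The lower 2 of the 5 abundance classes held 66.1% of the tested IDs that do not end in 0. Among the genes in these classes the shares were 49.2% of 193 and 41.8% of 4961 (Fisher's exact p = 0.0446). Both tests treat genes as independent, while log2 fold changes of adjacent tested IDs correlated at 0.222, so these p-values can be too small.

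The run of male-higher IDs under the prefix tetur09 consists of a stretch of 39 and one of 17, with 2 genes between them that did not pass the 2-fold threshold; 36 of the 56 male-higher genes had no read in any female library, and 7 of the 20 tested IDs just before the run were higher in males. A chance order of the calls is argued against, since the longest male-higher run in 100000 shuffled orders held 17 genes (permutation p = 1e-05, the smallest these shuffles can give). After thinning to equal depth 56 of the 58 were higher in males, so the calls do not rest on the extra reads of deeper male libraries. Thinning cannot add reads to females, where 36 of the genes had none, so it is no further test of the run. Reads of another organism carried in amounts that differ between male pools stay open: the total of the 56 genes varied by 4.08% (coefficient of variation) between male libraries, at percentile 88.49 of 10000 random sets of male-higher genes of like abundance, which decides neither way. A steady foreign source, reads shared between similar copies and a difference between the sexes themselves were not tested. The likeness of neighbours was not limited to the run: log2 fold changes of adjacent tested IDs of a prefix correlated across genes at 0.222 over 12693 pairs (Spearman 0.177; genes are not independent replicates), against a highest value of 0.04026 in 100000 shuffled orders (permutation p = 1e-05, the smallest these shuffles can give), and at 0.1879 without the run.

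The correlation of log2 fold changes fell with distance, to 0.107 at a distance of 2 IDs, 0.0665 at 5, 0.0529 at 10 and 0.0168 at 20. The longest female-higher run held 12 genes (permutation p = 0.0014).

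One adjacent pair of IDs, chosen after its values were seen in a scan of the most variable genes, traded places between libraries of the same sex. The gene tetur03g08450 had 2582 and 2141 CPM in male replicates 2 and 3 but 116 and 133 in replicates 1 and 4, while tetur03g08460 had 2.32 and 1.47 CPM in replicates 2 and 3 and 497 and 645 in replicates 1 and 4. In females, replicate 1 had 265 CPM of tetur03g08450 and 0.229 of tetur03g08460, and replicates 2, 3 and 4 had 13.3, 16.6 and 10.3 CPM of the first and 63.1, 74.3 and 53.0 of the second. Reads moved between similar copies with an unchanged total are argued against, since the pair's total varied by a factor of 4.217 between male libraries, where 95% of genes over 5 CPM vary by less than 1.49. Reads lost because of similar copies would change the total, and that was not tested. Libraries from broadly different stocks, an explanation narrowed to this wording after its value was seen, are argued against as well. Among all other IDs with a read, 0 parted the same libraries in both sexes by over 1.5-fold, and 0 of 20 flanking IDs did so among males. The flanking IDs were taken without a minimum level, so any with few reads could not have shown such a gap. A variant confined to this locus that differs in frequency between the pools may be behind the pattern, but no sequence was examined, and its share in the sex difference of tetur03g08450 (log2 fold change -4.02 ± 1.14 SE, adjusted p = 0.00397 by edgeR) is open.

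Low-abundance genes were more often higher in males. In the lower 2 of the 5 abundance classes, 2167 genes were higher in males and 1282 in females, a ratio of 1.69, against 1768 and 2185 (0.809) among the other 7731 genes. At log2 sizes of 1 to 2, 761 low-abundance genes were towards males and 541 towards females, and at 2.5 to 3.5 the numbers were 656 and 267. The lowest ratio under 4 other scalings was 1.618. These scalings put the median log2 fold change of all tested genes between -0.27 and -0.02, while it was -0.57 and -0.59 in the 2 low classes under TMM. A scaling shift of that size was not tried, so scaling is not decided for the excess within these classes. A change of scaling moves the log2 fold changes of all genes by about the same amount. The medians of the other classes were 0.24, 0.27 and 0.01 under TMM, from lower to higher abundance. These values argue against scaling as the source of the difference between low-abundance and other genes. The ratio was 1.668 after thinning to equal depth, and 1.705 without the 84 genes that rank among the 50 most abundant of either sex. Neither step removed the excess. The difference in mean depth was smaller than the spread between libraries, so thinning was a weak test of depth. Gene length and GC content were not analysed here. A difference between the sexes themselves stays open and untested, as do the differences in age and in the number of pooled animals.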
